A study of Rattus norvegicus with 24 samples.

How the data were processed

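RNA from the cortex of male Wistar rats was measured on 24 Illumina RatRef-12 version 1 beadchip arrays, with 4 arrays in each of 6 groups: sham-operated, vehicle and treatment animals at 8 h and at 24 h. Vehicle animals had permanent occlusion of a middle cerebral artery and an injection of 80% dimethyl sulfoxide (DMSO) into the cerebral ventricle. Treatment animals had the same injury and an injection of 30 mM ZM447439, an inhibitor of the Aurora kinases, in 80% DMSO. Groups and replicate numbers were taken from the sample titles. For the vehicle arrays the replicate numbers given in the descriptions differ from those in the titles, and the titles were used. The labels' protocols place the occlusion on the left side, whereas the tissue is labelled as right cortex, and nothing in the sources used here settles which is meant. The 24 arrays lay on 2 slides of 12 arrays, with 2 arrays of every group on each slide.

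The values used were intensities on a linear scale, as deposited by the authors in a table of 22523 probes with 1 column per array. How those intensities were background-corrected, scaled or normalized is not given in the sources used here, so their normalization stays unknown. A further 24 columns of non-normalized values carry only running numbers as names, match no sample by name, and entered no result. They were not assigned by order or by value, so a comparison of single genes between groups was not made here, which does not show that it could not be made. Columns were first compared with each other. Within each time point the 12 columns were 1 profile multiplied by 1 factor per array, so the table holds 2 distinct probe profiles, 1 for 8 h and 1 for 24 h. Which arrays the profile of a time point was derived from is not given in the sources used here.

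The design fixed before the data were examined called for limma models of sham, vehicle and treatment arrays with 4 arrays per group. Those models could not be fitted to the matched columns, because no probe varied between arrays of a time point apart from the array's factor. In their place, 2 kinds of comparison were made. The median intensity of each array was compared between groups on the log2 scale by exact two-sided permutation of the arrays (70 regroupings of 4 against 4, smallest possible p = 0.0286), with Benjamini-Hochberg adjustment over 7 comparisons. Arrays were regrouped across slides, so these p-values measure the spread between arrays with any difference between slides included. The labels do not say that each array is a separate animal. Each column was then divided by its median, the columns of a time point were reduced to 1 profile, and the log2 difference of each probe was taken as the 24 h profile minus the 8 h profile. With 1 profile per time point this difference has no replicate check and no p-value. The number of arrays limits the precision of the group comparisons.

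Gene symbols came from the platform annotation supplied with the data. Of the 22523 probes, 13793 had 1 symbol, 8730 had none and 0 had several. These gave 13337 genes, and 13752 of the named probes had a gene identifier in the reference gene table (assembly GRCr8, used for names only), through which 0 symbols changed. No coordinates are given, since no genome build is named. A gene with several probes was represented by the probe with the highest mean. A difference of at least 1.5-fold was counted as a size, not as a test.

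The 35 gene lists were fixed before the data were examined. The median difference of each list was placed among 10000 random lists of the same size, matched on mean intensity in 20 bins, and lists outside the central 95% were counted. This percentile describes the 2 profiles and is not a p-value. The planned rule for named genes needed the limma tests and was replaced, once the structure of the table was known and before any gene's value was seen. The replacement took the 12 largest positive and 12 largest negative differences among named probes above the median of mean intensity, up to 2 members per list with the largest absolute difference, and the Aurora kinase genes. Further genes named as examples of a list were chosen after their values were seen.

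The list procedure was tested on simulated data built on 13337 genes of the comparison of the 24 h and 8 h profiles. Of 100 unshifted lists of 20 genes, 7% fell outside the central 95%. Of 20 lists per shift, 10% were found above the 97.5th percentile at a log2 shift of 0.05, 75% at 0.15 and 100% at 0.30. These rates describe the simulated lists only and need not hold for the gene lists. The central range of matched random lists ran from -0.04 to 0.04 for mitosis genes and from -0.21 to 0.06 for striatum markers. The same shift is therefore not equally easy to find in every list, and members of a list may vary together.

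Alternatives for the profiles were quantile normalization, cyclic loess, scaling to the 75th percentile, subtraction of the 1st percentile with a floor of 8, normexp with an offset of 50 followed by quantile normalization, leaving out the lower 50% or the lower 75% of probes by mean intensity, and a 2-fold size. Alternatives for the array medians were the 75th percentile of the array, each slide alone, a replicate block and leaving out each array in turn. Further lists of hypothalamus, thalamus, hippocampus and cortical projection neuron markers and of clock output genes were written after the first list results. The analysis used R 4.3.3 with limma 3.58.1 for normalization, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.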

Results

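Gene expression in rat cortex was profiled after permanent occlusion of a middle cerebral artery, a model of ischemic stroke, with and without the Aurora kinase inhibitor ZM447439. Sham, vehicle and treatment groups were collected at 8 h and 24 h, with 4 arrays per group and 24 arrays in all. The design text gives no injection for the sham group, so the comparison of vehicle with sham joins occlusion and DMSO. The median intensity per array ranged from 65.3 to 115. Groups occupied the same positions on both slides, so position and group cannot be told apart.

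The first question was how the injury and the inhibitor altered expression at each time. No gene, Aurora kinase genes included, was compared here between sham, vehicle and treatment, because the 12 columns matched to samples at a time point carried the same probe profile. After 1 factor per array was removed, the largest departure of any of the 22523 probes from the common profile was 2.97e-07 on the log2 scale at 8 h and 2.87e-07 at 24 h. Over the 66 pairs of columns at each time, the largest SD of the log2 ratio was 7.27e-08 at 8 h and 7.33e-08 at 24 h. The 12 columns of a time were therefore counted as 1 profile, and the group comparisons below concern only the overall intensity of the arrays, that is, the factor, whose origin is not given in the sources used here.

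At 8 h the median intensity was 80.1 ± 4.69 (SD, n = 4) in sham, 83.2 ± 6.24 in vehicle and 75.9 ± 11.4 in treatment arrays. Vehicle differed from sham by 0.05 log2 (exact two-sided permutation p = 0.457), with 0.13 within slide 1 and -0.02 within slide 2. Treatment differed from vehicle by -0.14 (exact permutation p = 0.343), with -0.06 and -0.22 within the slides. Against sham, treatment differed by -0.09 (exact permutation p = 0.486), with 0.07 within slide 1 and -0.25 within slide 2. The adjusted exact permutation p was 0.567 for each of the 8 h comparisons.

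At 24 h the median intensity was 81.8 ± 6.39 (SD, n = 4) in sham, 99.5 ± 16.7 in vehicle and 91.2 ± 6.53 in treatment arrays. The vehicle mean was 0.27 log2, or 1.21-fold, above sham (exact permutation p = 0.114, adjusted p = 0.4), with 0.45 within slide 1 and 0.09 within slide 2. The vehicle arrays of slide 1 stood at 113 and 115, and those of slide 2 at 87.4 and 82.8. Treatment differed from vehicle by -0.11 (exact permutation p = 0.4, adjusted p = 0.567), with -0.27 within slide 1 and 0.04 within slide 2. Treatment differed from sham by 0.16 (exact permutation p = 0.114, adjusted p = 0.4), with 0.18 and 0.14 within the slides. This difference was 0.21 (unadjusted exact permutation p = 0.0286, the smallest possible) without sham replicate 2. Sham arrays at 24 h and 8 h differed by 0.03 (exact permutation p = 0.714, adjusted p = 0.714), with 0.05 and 0.01 within the slides. None of the 7 comparisons passed its test, before or after adjustment. With a smallest possible p of 0.0286, a comparison could not have passed alone after adjustment over 7. The adjusted values are therefore no evidence that the groups were alike. The vehicle to sham difference was 0.22 log2 larger at 24 h than at 8 h (exact permutation p = 0.227, 4900 regroupings), and treatment minus vehicle was less negative at 24 h, by 0.03 (exact permutation p = 0.896). Both of these tests regrouped the 8 h and 24 h arrays within each group, across slides. They are exact only if neither group changed with time, so they do not test the difference between times alone. The slides themselves had means of 91.1 ± 12.5 and 79.5 ± 7.41 (SD, n = 12).

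**Figure D1:**
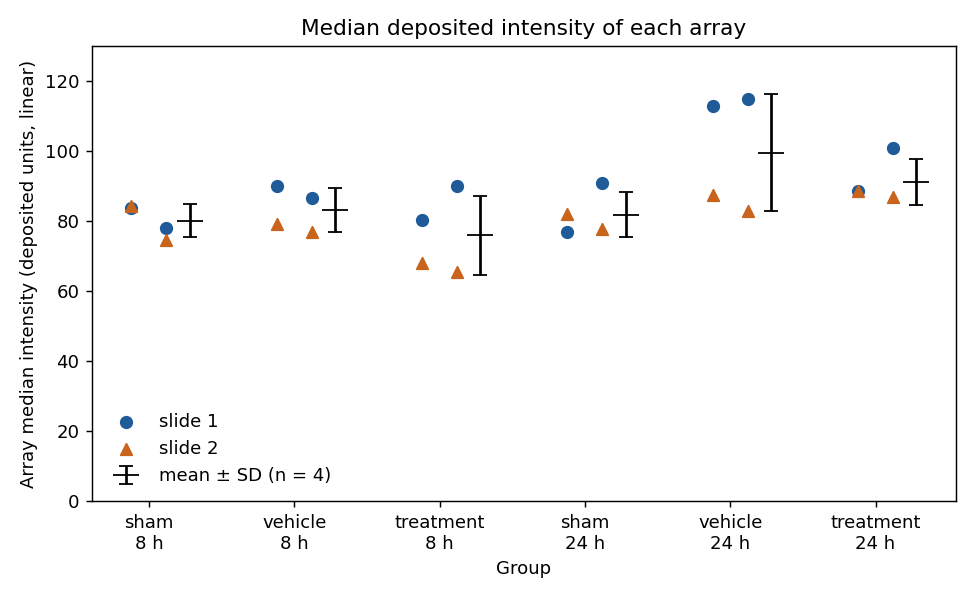
Median probe intensity of each array (vertical axis, linear intensity as deposited) for the 6 groups, with symbols for slide 1 and slide 2 and bars for the mean and SD of 4 arrays. The 24 h vehicle arrays of slide 1 stand at 113 and 115, above the other arrays.

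The second question was how the 24 h profile differed from the 8 h profile. Spp1, which encodes the secreted glycoprotein osteopontin, stood at 3.01 times the array median at 8 h and 20.3 times at 24 h, a 6.74-fold difference. Ttr, the thyroid hormone carrier transthyretin made by choroid plexus, stood at 5.10 and 30.1 times the median. Lgals3, the lectin galectin-3 of activated macrophages, was 3.81-fold higher at 24 h. The hypothalamic peptide gene Avp (vasopressin) stood at 2.93 and 9.97 times the median, and Oxt (oxytocin) at 1.10 and 3.54 times, its 8 h level being that of a typical probe. For Oxt and other genes under 1.5 times the array median in either profile, levels are given in place of a difference. At the other end, the metallothionein gene Mt1 stood at 85.2 times the median at 8 h and 32.4 times at 24 h, and the synaptic immediate early gene Arc at 14.5 and 6.20 times.

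Most probes differed little between the profiles. Of the 22523 probes, 139 were at least 1.5-fold higher at 24 h and 112 at least 1.5-fold lower, of which 121 and 91 carried a gene symbol. The split depended on the scaling: it was 174 higher and 87 lower after quantile normalization, 195 and 78 after cyclic loess, 184 and 88 with scaling to the 75th percentile, and 206 and 97 with normexp and quantile normalization. Subtraction of the 1st percentile gave 959 higher and 929 lower, and leaving out the lower 75% of probes gave 87 and 88. The SD of the log2 difference over probes was 0.17, and 89.3% of probes lay within 0.25 log2 of no difference. Across probes, which are not independent replicates, r was 0.995. Each profile is single and carries no replicate error, and the groups behind it are not known, so time after injury, treatment and sham surgery are not separated in it.

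The other high genes of the 24 h profile were Hspb1, a small heat shock protein (18.1 to 50.9 times the median), Lcn2, the acute-phase protein lipocalin-2 (6.41 to 17.6), S100a4 (log2 difference 1.43), S100a11 (1.30), the NADPH oxidase subunit gene Cyba (1.30), podoplanin gene Pdpn (1.29) and Tspo, a mitochondrial outer membrane protein abundant in activated microglia (1.26). The lowest difference of any probe, -1.61, belonged to a probe without a gene symbol. The other low genes were Fam151b (2.60 and 1.06 times the median), the peroxisomal membrane protein gene Pxmp4 (2.44 and 1.01), the chemokine gene Cxcl10 (2.73 and 1.21), the glucocorticoid receptor co-chaperone gene Fkbp5 (log2 difference -1.17), the neuronal pentraxin gene Nptx2 (-1.16), Gadd45g (-1.12), the mRNA decay factor gene Zfp36 (-1.10), Gpd1 (-1.10), the lipid transporter gene Mfsd2a (-1.05) and S100a8, an abundant neutrophil calcium-binding protein gene (-1.04).

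**Figure D2:**
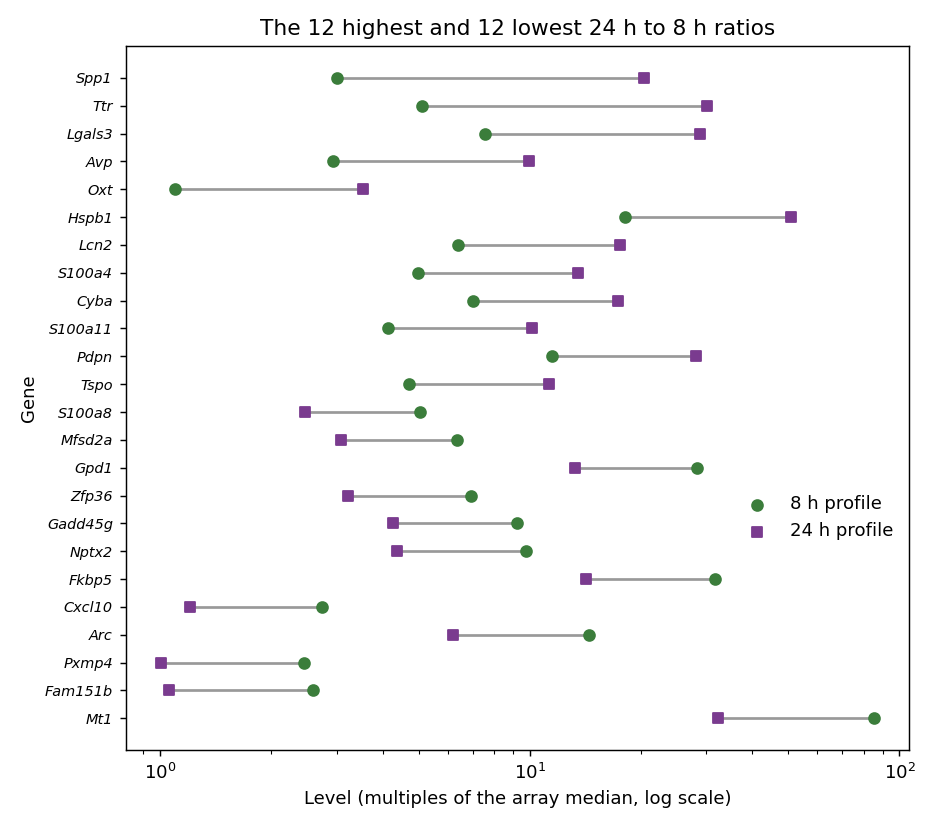
Level of the 12 genes with the highest and the 12 with the lowest 24 h to 8 h ratio among named probes above the median of mean intensity (horizontal axis, multiples of the array median, log scale), as circles for the 8 h profile and squares for the 24 h profile. Spp1 spans 3.01 to 20.3 and Mt1 85.2 to 32.4, each point being a single profile without an error bar.

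Of the 35 gene lists, 22 had a median outside the central 95% of matched random lists, 11 above and 11 below. With members that vary independently, 1.75 would be expected outside. Genes of a list may vary together, and some belong to several lists, so the count of 22 is not a test against chance. The size of a median depended on the setting for 17 of the 22 lists. It moved by over 1.5 times under at least 1 alternative other than scaling to the 75th percentile, and their ranges over those alternatives are given. Leaving out dim probes changes which members of a list are counted and not their values, and some ends of these ranges come from that. With profiles divided by their median, complement and acute-phase genes were highest. In this list 15 of 18 measured members were higher at 24 h, 9 of them at least 1.5-fold, and the list's median of 0.67 log2 lay above all 10000 random lists. The ranking depended on which members were counted. Without the lower 75% of probes, which leaves fewer members, reactive astrocyte genes reached 0.94, above the complement range of 0.67 to 0.87. A2m differed by 1.22, Serping1, the C1 inhibitor, by 1.04, C2 by 1.04 and the C1q chain gene C1qb by 0.87. Microglia and macrophage markers were higher in 18 of 20 members (median 0.35, 0.35 to 0.655 over the alternatives, above all random lists), with Aif1 at 15.7 and 33.3 times the median, the Fc receptor gene Fcgr3a at a difference of 1.13 and its signalling chain Fcer1g at 0.93. Interferon-response and antigen-presentation genes were higher in 24 of 33 members (median 0.12, 0.12 to 0.27 over the alternatives, above all random lists). They included the class II gene RT1-Da (0.86), the immunoproteasome gene Psmb8 (0.76) and the antiviral GTPase gene Mx1 (1.31 and 2.35 times the array median), whereas the transcription factor gene Irf1 was lower (-0.67). The list does not hold the chemokine genes Cxcl10 and Cxcl11, which were counted with the cytokines and were lower at 24 h.

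Reactive astrocyte genes were higher in 14 of 18 members (median 0.17, 0.16 to 0.94 over the alternatives, above all random lists). The intermediate filament gene Gfap stood at 124 and 241 times the array median, Vim differed by 1.05 and the protease inhibitor gene Timp1 by 0.91. Hspb1 and Lcn2 also belong to this list. General astrocyte markers lay inside the random range (90.4th percentile), with the gap junction genes Gjb2 at 1.07 and Gjb6 at -0.66. Endothelial and pericyte markers were higher in 14 of 17 members (median 0.15, 0.12 to 0.39 over the alternatives, 99.99th percentile), with the smooth muscle gene Tagln at 1.14 and Anpep at 1.06 and 1.53 times the array median. Meninges and fibroblast genes were higher in 11 of 15 members (median 0.08, 0.08 to 0.24 over the alternatives, 99th percentile), with Igfbp2 at 1.03 and Fbln1 at 0.73. The brightest members of this list, Ptgds (-0.30) and Igf2 (-0.46), were lower.

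Most measured cell-cycle genes were higher in the 24 h profile. G1 and DNA replication genes were higher in 21 of 28 members (median 0.15, 0.15 to 0.33 over the alternatives, above all random lists), including the replicative helicase gene Mcm6 (0.91) and the cyclin gene Ccnd1 (0.66), while the helicase gene Mcm3 stood at 0.963 and 1.58 times the array median. Mitosis genes were higher in 25 of 32 members (median 0.12, 0.11 to 0.515 over the alternatives, above all random lists), and 1 member, the mitotic kinase gene Cdk1, passed 1.5-fold at 1.14 and 2.09 times the median. The mean level of 13 of the 32 members over both profiles was below the array median. Of the brightest members by mean level, Aurkc (-0.44), Tpx2 (-0.26) and Incenp (-0.13) were lower and Prc1 (1.44 and 1.83 times the median) was higher. Only Aurkc and Tpx2 stood above 2 times the median in both profiles, so most of the list was dim. The spindle motor gene Kif11 stood at 0.947 and 1.36 times the median, with a difference of 0.00 at its second probe. Among the targets of ZM447439, Aurka stood at 1.11 and 1.14 times the median, Aurkb at 1.40 and 1.77 times, and Aurkc at 3.43 and 2.53 times. The p53 targets and cell-cycle inhibitors were lower in 15 of 20 members (median -0.11, -0.25 to -0.08 over the alternatives, 0.43rd percentile), with Gadd45g the member past 1.5-fold and Gadd45b at -0.51, and the list lay inside the random range without the lower 50% or 75% of probes.

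The lists of immediate early, activity- or injury-induced, glucocorticoid-responsive, NF-kB and cytokine genes had lower medians in the 24 h profile. Neuronal activity and hormone levels were not measured. Immediate early genes were lower in 23 of 24 members (median -0.34, -0.67 to -0.24 over the alternatives, below all random lists), with Fos at 6.03 and 3.03 times the array median and Egr1 at 41.3 and 23.0. Growth factors and neuropeptides induced by activity or injury were lower in 12 of 21 members (median -0.15, -0.38 to -0.11 over the alternatives, 0.49th percentile), Nptx2 and the neurotrophin gene Bdnf (-0.98) among them. Glucocorticoid-responsive genes were lower in 16 of 17 members (median -0.44, below all random lists), including Fkbp5 and the kinase gene Sgk1 (-0.79), with Lcn2 as the higher member. NF-kB targets and endothelial activation genes were lower in 13 of 17 members (median -0.11, -0.46 to -0.11 over the alternatives, 1.35th percentile), with Cebpb at -0.77 and the inhibitor gene Nfkbia at -0.70. Cytokines and chemokines were lower in 16 of 28 members (median -0.07, -0.10 to 0.04 over the alternatives, 2.23rd percentile), but the list lay inside the random range under all 6 alternatives that could move its percentile and its median turned positive after cyclic loess and without the lower 75% of probes. Cxcl10 and Cxcl11 (2.74 and 1.36 times the array median) were its lowest members.

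Neuron markers were lower in 22 of 25 members (median -0.18, 0.35th percentile), with the neurofilament gene Nefl at -0.46 and the kinase gene Camk2a at -0.35. Voltage-gated ion channels were lower in 22 of 29 members (median -0.13, -0.23 to -0.06 over the alternatives, 0.485th percentile), with Kcnh1 at -0.50 and Kcnd3 at -0.36. Glutamate and GABA receptors were lower in 15 of 23 members (median -0.13, -0.25 to -0.05 over the alternatives, 1.97th percentile), with Gabbr2 at -0.39 and Grik5 at -0.52, although a second Grik5 probe showed 0.01, and the list lay inside the random range under 5 of the 6 alternatives that could move its percentile. Oligodendrocyte markers were lower in 15 of 18 members (median -0.25, 0.02nd percentile), with the myelin genes Mal (-0.73) and Mobp (-0.61) past 1.5-fold. Striatum and choroid plexus markers lay on the opposite side. Striatum markers were higher in 11 of 12 members (median 0.29, above all random lists), from Adora2a at 1.25, Tac1 at 1.11 and Rgs9 at 1.05 to Ppp1r1b at 0.07 and Drd2 at -0.04. Choroid plexus and ependyma markers were higher in 12 of 13 members (median 0.30, 0.30 to 0.84 over the alternatives, above all random lists), with Ttr highest and Sostdc1 at 0.985 and 2.06 times the array median. Only Ttr and Rarres2 (0.67) of this list stood above 2 times the median in both profiles, so most of it was dim. Erythroid genes were lower in 4 of 6 members (median -0.22, -0.43 to -0.18 over the alternatives, 0.43rd percentile), with the globin genes Hbb-b1 at -0.51 and Hba-a1 at -0.43, and the list lay inside the random range after subtraction of the 1st percentile.

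Unfolded protein and integrated stress response genes had a median of 0.04 (0.04 to 0.14 over the alternatives, 98.9th percentile) with 16 members higher and 14 lower, from the endoplasmic reticulum chaperone genes Canx (0.56) and Pdia6 (0.49) to the transcription factor gene Atf3 (1.56 and 1.14 times the array median). The other lists lay inside the random range. Apoptosis genes were at the 93.2nd percentile, with Bcl2a1 at 0.80 and Casp1 at 0.67, and hypoxia-inducible genes at the 87.1st, with the lactate transporter gene Slc16a3 at 0.92 and Bnip3 at -0.67. Extracellular matrix genes were at the 80.7th percentile despite Spp1 and Lgals3, but outside the range, on the higher side, without the lower 75% of probes. Oxidative stress genes were at the 73.9th, with Mt1 and Txnrd1 (-0.79) lowest. Heat shock genes were at the 49.6th percentile, where Hspb1 was higher and Cryab lower (-0.86). Neutrophil markers were at the 14.4th percentile, with S100a8 lower and the oxidase gene Ncf1 higher (0.83), and T and B lymphocyte markers at the 54.5th, with Cd8a at 0.777 and 0.883 and Prf1 at 1.12 and 1.01 times the array median. Cholesterol synthesis genes were at the 41.0th percentile (Ebp 0.28, Dhcr7 -0.27), GABAergic interneuron genes at the 33.0th (Crh -0.48, Cck -0.42), oligodendrocyte progenitor markers at the 23.6th (Vcan -0.21, Pdgfra -0.15), oxidative phosphorylation genes at the 20.3rd (Cox8a -0.27, Ndufs3 -0.27) and circadian clock genes at the 12.6th (Per1 -0.59, Bhlhe40 -0.53). Without the lower 75% of probes the clock list lay outside the range, on the lower side.

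**Figure D3:**
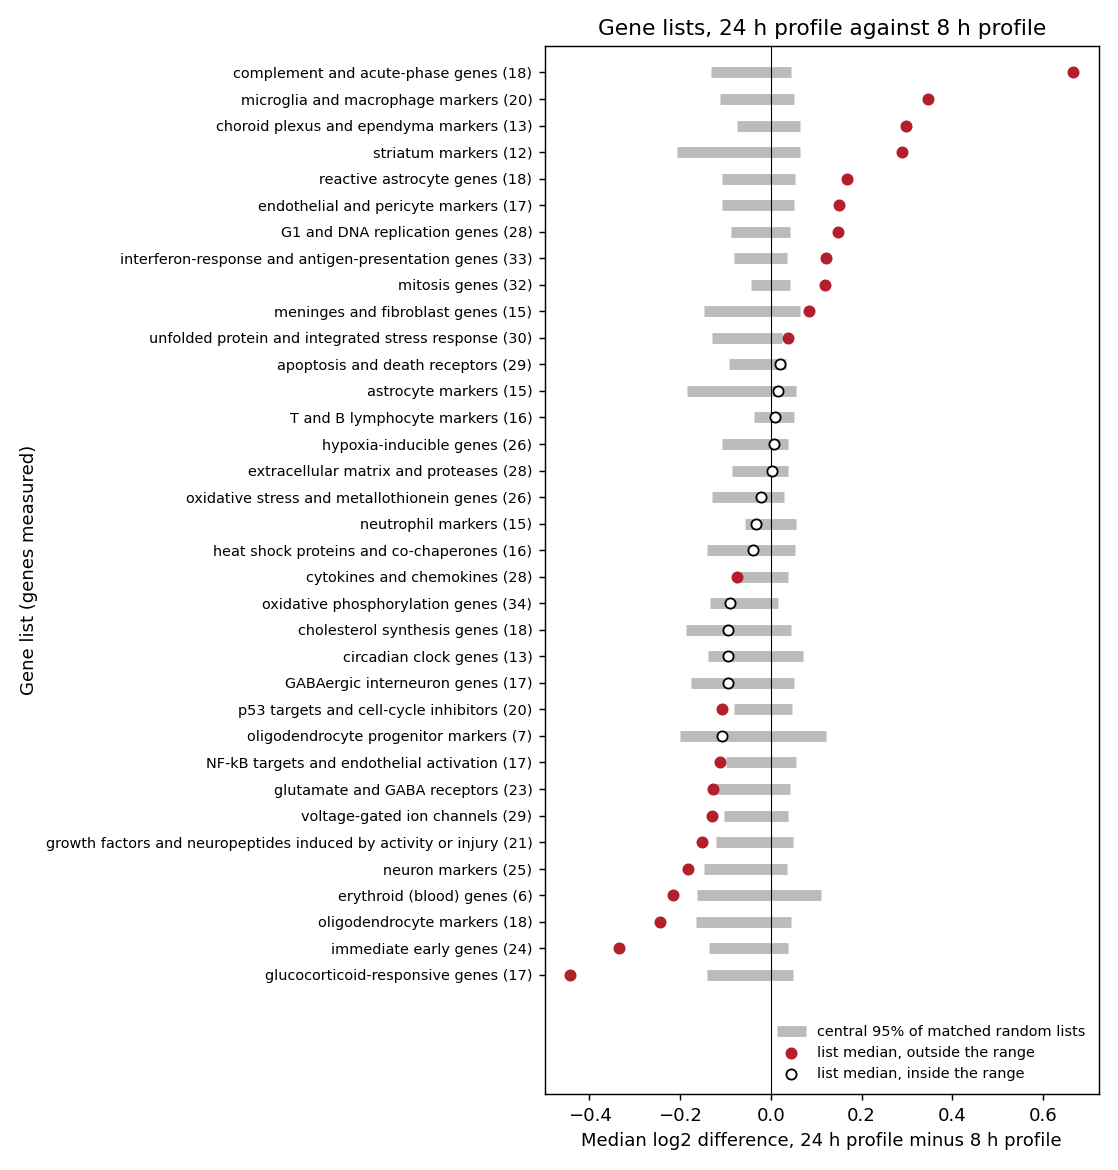
Median log2 difference between the 24 h and 8 h profiles (horizontal axis) for the 35 gene lists, with grey bars for the central 95% of 10000 matched random lists. Complement and acute-phase genes lie highest at 0.67 and glucocorticoid-responsive genes lowest at -0.44.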

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

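The array medians were chosen as a measure after the structure of the table was seen. Among the 6 groups, 1 held an array far from the others: in the treatment group at 24 h, replicate 2 had a median intensity of 101, against 86.7 to 88.6 in the other arrays. Its gap to the nearest array was 0.866 of the group's range, above the critical value of Dixon's test for 4 arrays, which chance exceeds in about 1 of 20 groups.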

How the results depend on the processing

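The alternatives here were chosen after the data were examined, except cyclic loess and leaving out dim probes. None of the 7 group comparisons of array medians passed its exact permutation test as reported. Within single slides, vehicle against sham at 8 h turned to -0.024 on slide 2, treatment against sham at 8 h to 0.073 on slide 1, and treatment against vehicle at 24 h to 0.043 on slide 2. The cause of these changes within slides was not tested. Sham at 24 h against 8 h turned to -0.025 with the 75th percentile of the array. With 1 shared profile, that percentile is the median times 1 constant per time point. It could not move a comparison within a time point, and the sham change follows from the shapes of the 2 profiles. With each array left out in turn, the ranges were -0.021 to 0.059 for sham over time, 0.107 to 0.208 for treatment against sham at 24 h and -0.173 to -0.020 at 8 h, -0.196 to -0.039 for treatment against vehicle at 24 h and -0.226 to -0.073 at 8 h, and 0.195 to 0.353 for vehicle against sham at 24 h and 0.014 to 0.090 at 8 h. Treatment against sham at 24 h came to pass, at 0.208, only without sham replicate 2, and by an exact permutation p that was not adjusted over the 7 comparisons. Sham over time changed sign without sham 24 h replicate 2 (-0.021) or sham 8 h replicate 4 (-0.00432). With a replicate block, vehicle against sham at 24 h stayed at 0.27 (exact sign-flip p = 0.125, the smallest that 4 pairs allow), so the block could change no call.

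Probes at least 1.5-fold apart numbered 959 higher and 929 lower after subtraction of the 1st percentile, which magnifies dim probes. Without the lower 75% of probes 87 were higher and 88 lower, since fewer were compared, and at 2-fold 32 were higher and 16 lower. Scaling to the 75th percentile cannot move a list against its random lists and is not counted for them. Of 205 list values under the other alternatives, 189 kept their side of the random range, 14 moved inside it, 2 moved outside and 0 reversed from one outer side to the other. The cytokine list moved inside at -0.019 with quantile normalization, 0.009452 with cyclic loess, -0.104 with the 1st percentile subtracted, -0.020 with normexp, -0.0747 without the lower 50% of probes and 0.040 without the lower 75%. Glutamate and GABA receptors moved inside at -0.0748 with quantile normalization, -0.046 with cyclic loess, -0.0786 with normexp, -0.171 with the 1st percentile subtracted and -0.143 without the lower 50%. Erythroid genes moved inside at -0.242 with the 1st percentile subtracted, and p53 targets at -0.168 and -0.214 without the lower 50% and 75%. Extracellular matrix genes (0.22) and circadian clock genes (-0.47) moved outside without the lower 75%. The cause was not tested. Of 551 values of named genes, 518 stayed within 1 SD of all probe differences, 33 moved further and 0 reversed. A reversal was counted only for genes at least 1.5-fold apart. Leaving out dim probes keeps a gene's difference as it was, and scaling to the 75th percentile adds 1 constant smaller than that SD. The values under these settings could not move, so the count of 518 overstates how stable the genes were. Array weights, other variance models, other adjusted p thresholds and other correlations between genes were not run, because the limma models could not be fitted to the matched columns.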

Other observations

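The tests on proportional columns and those on list medians after cyclic loess were chosen after those results were seen. The marker lists of brain regions and clock genes, and their tests, were added after the list results of the report. The rule that a list of mostly dim genes excludes nothing was applied to the clock test after its value was seen, and the percentile after cyclic loess was likewise set aside after it was seen.

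Several hypothalamic peptide genes besides Avp and Oxt were higher in the 24 h profile, among them Trh at 2.01 and 3.14 times the array median and Pmch, the melanin-concentrating hormone precursor, at 1.11 and 1.65 times. Hypothalamus markers were higher in 14 of 19 members (99.2nd percentile), a list that holds Avp, Oxt and Tac1, seen high beforehand, and without these 3 the median lay inside the random range (16 members, 96.1st percentile). Cortical projection neuron markers were lower in 14 of 16 members (median -0.24), including the vesicular glutamate transporter gene Slc17a7 (-0.34) and the homeobox genes Emx1 (-0.30) and Emx2 (-0.33). Thalamus markers lay at the 58.2nd percentile (13 members), although the calcium channel gene Cacna1g differed by -0.96, and hippocampus markers at the 63.1st (11 members), with Grp at -0.39. Clock output genes lay at the 26.2nd percentile (7 members).

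The first pattern is the shared profile of all arrays of a time point. Arrays measured separately and normalized between arrays would leave a spread between columns, and the largest SD of 7.33e-08 argues against that. A reference profile per time point, scaled by 1 factor per array and deposited in place of the measurements, would leave only rounding, as the largest departure of 2.97e-07 did. This candidate explanation came from the same values that it was tested on. No biological explanation was tested.

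The second pattern is the higher level of striatum, choroid plexus and hypothalamic peptide genes at 24 h. More subcortical tissue in the 24 h profile may account for it, and would raise other hypothalamus markers and dilute cortical ones. Cortical projection neuron markers lay at percentile 0 of random lists, and at percentile 0.02 over the 11 members that no earlier list held, which goes with dilution, but neuron markers as a whole were also low, so a loss of cortical neuronal transcripts would give the same value. Striatal genes did not move alike, with Adora2a at 1.25 but Drd2 at -0.04 and Ppp1r1b at 0.07, although Ppp1r1b was already at 39.5 times the array median and a small share would be hidden there. Thalamus markers, from another subcortical region, were not raised as a list (58.2nd percentile, 13 members). The 17 hypothalamus markers without Avp and Oxt lay at percentile 96.955, just inside the random range, and most were dim, as was Oxt at 8 h, so this part, like injury and treatment, stays open.

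The third pattern is the higher microglia, reactive astrocyte, complement and interferon lists beside the lower immediate early and glucocorticoid lists. Cyclic loess could not decide whether an intensity-dependent shift was the whole cause. It removes only a trend with intensity, and the random lists were already matched on intensity. After loess the microglia list's median was 0.38 (0.35 before). That of immediate early genes was -0.24 (-0.34 before), so part of it may follow intensity. The microglia list's percentile was 100 before and after loess, which adds nothing for the same reason. Before loess, the microglia median already lay above all random lists of matched intensity, and the immediate early median below all of them. Intensity alone, as finely as it was matched, therefore did not give the medians of these lists. A different time of day at collection could not be excluded. The clock output genes' median absolute difference of 0.09, at percentile 31.75, met the bound for excluding it. That bound was set before this value was seen, but after the result of the circadian clock list, which shares genes with this list. Moreover, 5 of the 7 genes stood under 2 times the array median, and of the brighter genes Per2 differed by -0.44 and Nr1d1 by -0.02. Time after injury, surgery and treatment remain open and untested.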
